A study of Mus musculus with 26 samples.

How the data were processed

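Gene expression was measured on 26 arrays, 1 per sorted sample. Per the labels' protocols, RNA was extracted with Trizol, amplified with a whole-transcriptome kit for small amounts of RNA and labelled with biotin. The authors deposited 1 table of intensity values for 45101 probe sets, processed with RMA per the submitters' processing notes, whose version is not given in the sources used here. RMA corrects background, normalises the arrays by quantiles and combines the probes of a set. The deposited intensities were on a linear scale, from 4.75 to 49676, and their log2 was taken here.

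Probe sets were named through the platform's annotation, with symbols updated through gene identifiers for 34741 probe sets. Of the probe sets 34945 named 1 gene, 932 several and 9160 none, and 64 were controls. Only probe sets naming 1 gene were tested as genes. For each of 18193 genes the probe set with the highest mean over all arrays was used. Other probe sets were compared for 75 differences of 50 genes, of which the text prints most. These genes were selected from those that the naming rule below allowed. Of the 75 differences 45 had other probe sets. In 5 of these at least 1 other probe set had the opposite sign (Tcf4 at day 7, and Inhba, Rrm2b, Acta2 and Aff4 at day 5). Probe sets without a single gene name, 10092 in number, were tested in another fit, of all 45037 probe sets other than controls and adjusted over these. With all arrays at equal weight none of the 45037 was called in any contrast. With array weights 143 of the 10092 were called at day 5 and 762 at day 7, and 483 and 891 for the controls of days 5 and 7 over day 3. No genome coordinates were used.

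Groups were taken from the sample titles. All 26 arrays entered 1 limma fit (limma 3.58.1, R 4.3.3) with 6 group means, moderated by eBayes. The contrasts were Cre minus control on each day, the differences between these, and control arrays of days 5 and 7 against day 3. P-values were adjusted over all genes by Benjamini-Hochberg, with a threshold of 0.05. Gene lists, 28 in number with 667 symbols of which 605 were measured, were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, adjusted over the lists. The lists overlap, with Hoxa5, Hoxa7, Hoxa9 and Hoxa10 also among the MLL-fusion targets.

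The design, the lists, the naming rule and the first set of alternatives were fixed before the data were examined. For each day the rule named Dot1l, the 10 genes with the largest change in each direction among those past the threshold whose Cre and control arrays did not overlap, and up to 4 members of each list with the smallest unadjusted p. Measured members of the HOXA and DOT1L complex lists could be named as well. For the other contrasts it named the 5 largest changes in each direction past the threshold, of which there were none. The first alternatives included a replicate block, another normalisation, other choices of probe set, array weights and leaving out each array in turn. Alternatives chosen after seeing the data left out the narrow arrays or dim genes, took the spread of an array as a covariate, or joined array weights or the block with another choice. The exact permutation tests of list means were also added then.

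The pairing of replicate numbers was checked by correlating residuals across genes. At day 5 the same-numbered arrays correlated at 0.447, 0.376, 0.357, 0.666 and 0.644, all over 0.1, which met the rule for pairing. Arrays of different numbers reached 0.767, however, and for Cre arrays 2, 4 and 5 the closest control had another number. Same-numbered arrays correlated at 0.045, 0.148, -0.100 and 0.609 at day 3, and at 0.110, -0.407 and 0.458 at day 7. Arrays 1 and 2 of day 5 were narrow in both the Cre and the control group, so the check cannot tell pairing from a shared spread. No arrays were identical, and the highest correlation between 2 arrays across probe sets was 0.993.

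The limma code was tested on 20 simulated data sets of the day 7 comparison with 18193 independent genes. With noise as on the real arrays, the equal-weight fit recovered on average 0.2% of genes changed by 1 and 15.6% of those changed by 2 (log2), and none of its calls was false. Array weights recovered 29.5% and 83.0%, with 2.89% false calls. With equal noise the equal-weight fit recovered 5.25% and 52.0%. For the HOXA list, shifted by -1 in all of its genes under equal noise, camera called it in 19 of 20 data sets. These simulations hold no correlation between genes and so do not show how the weighted fit behaves on the real arrays.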

Results

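The series followed gene expression in mouse MLL-AF9 leukemia cells in which the gene for the H3K79 methyltransferase Dot1l could be deleted by Cre recombinase. MLL-AF9 is a fusion oncoprotein that drives acute myeloid leukemia. Leukemia cells marked with GFP and carrying floxed Dot1l alleles were taken from leukemic mice. They were then transduced with a retrovirus carrying Cre and YFP, or with a control virus carrying YFP alone. Cells positive for both markers were sorted 3, 5 and 7 days later, and total RNA from each sort was hybridised to 1 array. The Cre groups held 5 arrays at day 3, 5 at day 5 and 3 at day 7. The control groups held 4, 5 and 4 arrays, which made 26 in all. The labels do not say whether the arrays of a group came from separate mice or cultures, so the p-values measure the spread between these arrays. The number of arrays limits the precision of every value. The median intensity per array was 85.1 to 98.7.

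The arrays differed in their spread of values, and they were divided here at 3.3 without a clear gap there. On 9 arrays the interquartile range of the log2 intensities was at most 3.23, and on the other 17 it was at least 3.35. The narrow arrays had BioB hybridisation-control levels of 12.05 to 13.70 (log2), against 10.41 to 11.77 on the wide arrays. Their median correlation with the other arrays, taken across genes, was 0.866 to 0.936, against 0.955 to 0.971. Each group held 1 or 2 narrow arrays, and the first principal component, with 34.9% of the variance, followed the spread. Within the wide arrays the BioB level was also lower at a larger spread (r = -0.77), while within the narrow arrays it was not (r = 0.23). The split at 3.3 was set after the values were seen, so narrow and wide name the sides of a cut.

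**Figure D1:**
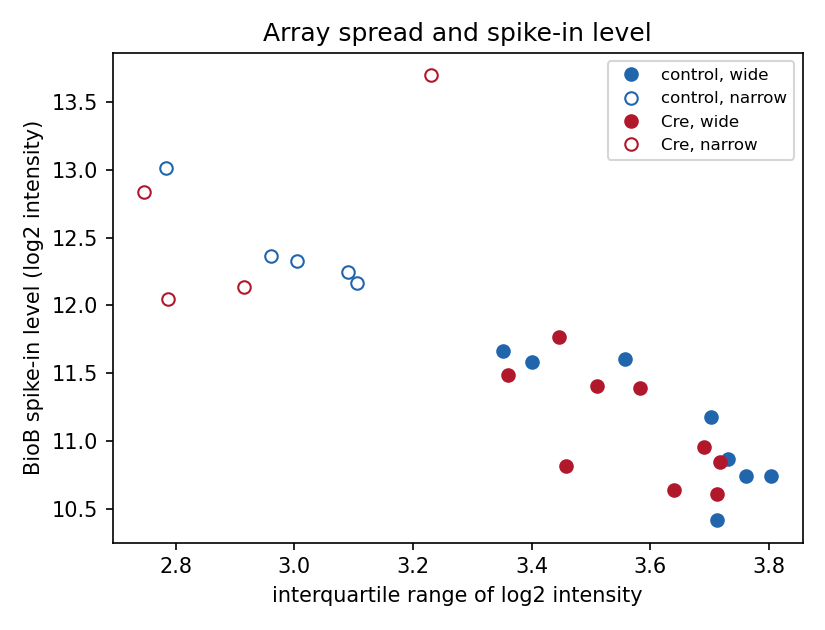
Each point is 1 of the 26 arrays, with the interquartile range of its log2 intensities on the x axis and its BioB spike-in level (log2 intensity) on the y axis. The 9 narrow arrays (open points) lie at a spread of at most 3.23 and a BioB level of at least 12.05, in both the Cre (red) and the control (blue) arrays.

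Dot1l itself was read first. Its probe set with the higher mean had a mean log2 intensity of 7.64 ± 0.23 (SD, n = 5) with Cre and 8.09 ± 0.10 (SD, n = 4) in the control at day 3. The difference was -0.45 ± 0.18 (SE) at day 3 and -0.47 ± 0.17 at day 5, with limma adjusted p of 1.00 and 0.575. At day 7 it was -0.09 ± 0.20, with an adjusted p of 1.00. The other Dot1l probe set differed by -0.23, -0.39 and -0.58 on the 3 days. None of these differences passed the test over all genes with all arrays at equal weight. On the first probe set every Cre array of day 3 lay below every control array, and at day 5 the Cre array was lower in each same-numbered pair. With array weights the day 5 difference was -0.57 ± 0.11 (SE, adjusted p = 0.00587). It passed in 5 of 46 alternatives at day 5 and 2 of 46 at day 3, all of them with array weights. The sources used here do not say which part of the gene Cre removed, so these probe sets do not check the labels.

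At day 3 no gene and no gene group passed every form of the test. The granulocyte markers had a median log2 difference of 0.52 between Cre and control, with 22 of 23 measured members positive. Among them, the neutrophil elastase gene Elane differed by 0.61 ± 0.27 (SE) and the haptoglobin gene Hp by 0.51 ± 0.28. The 9 measured HOXA cluster genes, homeobox transcription factors of blood progenitors, had a median of -0.23. Tm7sf2, a sterol reductase gene, differed by 0.99 ± 0.34, the cytokine receptor gene Csf2rb2 by 1.21 ± 0.49 and Id2, an inhibitor of DNA binding among the MLL-fusion targets, by 1.08 ± 0.49. Without 1 array of that day Elane differed by 0.38 (Cre array 1) or 0.40 (control array 4), Tm7sf2 by 0.57 (control array 1) and Id2 by 0.72 (control array 2).

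Of the 18193 genes tested with limma at day 3, 0 passed an adjusted p of 0.05, and 257 had an unadjusted p under 0.05 (1.41% of genes). Of the 28 gene lists, 11 passed camera with its preset correlation, all toward higher values in Cre, while 0 passed with an estimated correlation and 0 passed fry. For the granulocyte markers the adjusted p was 3.19e-06, and 0.502 with an estimated correlation, in a range of 1.89e-14 to 0.993 over the alternatives. For the monocyte and macrophage markers it was 0.00580, and 0.632 with an estimated correlation. The other 9 lists were the p53, NF-kB, ribosome biogenesis, ribosomal protein, glycolysis, cholesterol, lysosome, cytokine receptor and stress genes, and their adjusted p with an estimated correlation ran from 0.502 to 0.764. The mean of the granulocyte list relative to the other genes, 0.62, was 0.34, 0.32, 0.98 and 0.35 without Cre array 1, 2 or 3 or control array 4 of that day. With array weights 12 lists passed, 9 toward higher and 3 toward lower values. The lower ones were the HOXA (median -0.52, adjusted p = 1.42e-05), MLL-fusion target (0.0106) and mitosis (0.00752) lists, and 0 passed with an estimated correlation. Over 51 alternatives the HOXA list passed in 9 and the MLL-fusion targets in 8. The HOXA mean relative to the other genes was -0.24 (adjusted p = 0.372), and without Cre array 3 of that day it was -0.41 (adjusted p = 0.0358). Leaving out 1 array of the day ended between 2 and 7 of the list calls, most of them without control array 2. The Cre arrays all lay above the controls in 55 genes and all below in 79, which is 0.737% of genes against 1.59% by chance. No member of any list passed when adjusted over the list alone or over all genes.

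At day 5 the HOXA cluster genes fell as a group and the granulocyte markers rose as a group. All 9 measured HOXA genes were lower with Cre, with a median log2 difference of -1.44. Among them Hoxa2, Hoxa4 and Hoxa13 lay near or below the median level of all probe sets at day 5 (6.52). Hoxa13 differed by only -0.32, with overlapping arrays. The mean of the list per array was 7.36 ± 0.39 (SD, n = 5) with Cre against 8.66 ± 0.21 (SD, n = 5) in the control. Hoxa11 differed by -2.17 ± 0.40 (SE), Hoxa5 by -2.03 ± 0.45, Hoxa10 by -1.88 ± 0.44 and Hoxa9 by -1.44 ± 0.36. Of the 23 measured granulocyte markers 22 were higher, with a median difference of 1.88. Their mean per array was 11.52 ± 0.59 (SD, n = 5) with Cre and 9.63 ± 0.84 (SD, n = 5) in the control.

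The HOXA cluster had a camera adjusted p of 3.49e-15, and 0.00594 with an estimated correlation, and fry gave 0.00317; over the alternatives it ran from 1.06e-18 to 0.0556. When adjusted over the list alone, 7 HOXA genes were lower, and 0 passed over all genes. The granulocyte list had an adjusted p of 3.39e-18, and 0.0379 with an estimated correlation, in a range of 7.28e-26 to 0.0889 over the alternatives. Of its members 15 were higher when adjusted over the list alone, and 0 passed over all genes. These included Fcnb, a ficolin of granules, at 3.86 ± 0.98 (SE), the chitinase-like gene Chil3 at 4.13 ± 1.12, Anxa1 (annexin A1) at 3.25 ± 0.83 and the chemokine receptor gene Cxcr2 at 1.34 ± 0.34. Csf3r, the receptor for G-CSF, was also among them at 1.22 ± 0.38.

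Known targets of MLL fusion proteins fell as a group at day 5 as well. Of 27 measured targets 20 were lower with Cre, with a median log2 difference of -0.54. The camera adjusted p was 3.69e-09, and 0.0140 with an estimated correlation, in a range of 5.13e-11 to 0.0556 over the alternatives. Adjusted over the list alone, 10 were lower and 1 was higher, and 0 passed over all genes. Genes for the transcription factors Mef2c and Meis1 differed by -2.14 ± 0.49 (SE) and -1.88 ± 0.49, the survival gene Bcl2 by -1.56 ± 0.46 and Tcf4 by -1.37 ± 0.42. The list of leukemia self-renewal genes, which shares members such as Hoxa9, Meis1 and Mef2c with the targets, had a median of -0.43, an adjusted p of 2.22e-07 and 0.0140 with an estimated correlation. Over the alternatives that p ran from 2.33e-08 to 0.0556. Of its 18 members 6 were lower when adjusted over the list alone, and 0 passed over all genes.

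The other lists called at day 5 with the preset correlation were lost with an estimated one. The monocyte and macrophage markers had a median of 0.76 (adjusted p = 0.388 with an estimated correlation), with Msr1, a scavenger receptor gene, at 1.46 ± 0.53 (SE) and the chemokine gene Ccl6 at 1.80 ± 0.68. The p53 and DNA damage genes had a median of 0.34 (adjusted p = 0.195 with an estimated correlation). Adjusted over the list alone, 2 of them were higher and 1 was lower, and 0 passed over all genes. Plk2 differed by 1.38 ± 0.39, the growth arrest gene Gadd45a by 1.23 ± 0.37 and Rrm2b, a ribonucleotide reductase subunit gene, by -1.07 ± 0.36, though 2 of 3 other Rrm2b probe sets had the opposite sign. DNA replication genes, with Mcm10 at -0.93 ± 0.46, had a median of -0.32, and mitosis genes, with Prc1 at -0.90 ± 0.50, one of -0.27. Both had an adjusted p of 0.641 with an estimated correlation. For the megakaryocyte, stroma, NF-kB, ribosome biogenesis, ribosomal protein and cholesterol lists that p ran from 0.411 to 0.646. Without Cre array 2 of that day Msr1 differed by 0.96, Rrm2b by -0.66, Mcm10 by -0.46 and Prc1 by -0.42, and 6 of these list calls ended.

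Of the 18193 genes tested with limma at day 5, 2 passed, and 992 had an unadjusted p under 0.05 (5.45%). Inhba, which encodes an activin subunit, was higher with Cre by 4.66 ± 0.77 (SE, adjusted p = 0.0468), and higher in 5 of 5 Cre arrays than in any control array of that day. Its other probe set differed by -0.03. The clone-named gene D130051D11Rik differed by -1.96 ± 0.34 (adjusted p = 0.0475) and was lower in 5 of 5 Cre arrays than in any control array. Neither gene passed in the fit of all 45037 probe sets. The Cre arrays all lay above the controls in 136 genes and all below in 103, which is 1.31% of genes against 0.794% by chance. Whether the replicate numbers pair the arrays is not settled, and with the number as a block 0 genes passed at day 5. In a fit of the day 5 groups alone with that block 68 passed. In the fit of all arrays 7 passed with the number as a random effect, which joins the same number across days. With array weights 316 genes passed, with 8 HOXA genes and 14 granulocyte markers among them. Leaving out single arrays gave 0 to 13 genes, the most without Cre array 1 of day 7, when Hoxa11 and Mef2c passed as well (adjusted p = 0.0193 and 0.0396).

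**Figure D2:**
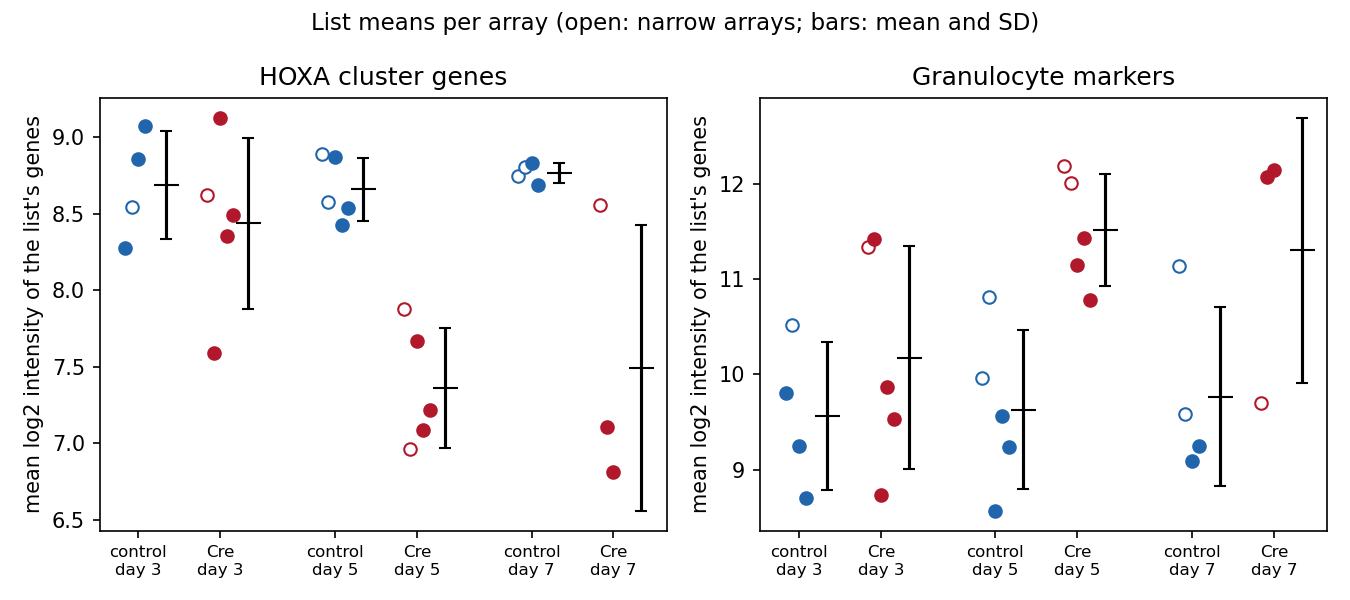
Each point is 1 array, with the mean log2 intensity of the 9 HOXA cluster genes (left) or the 23 granulocyte markers (right) on the y axis and the group on the x axis; open points are narrow arrays, and bars give the mean and SD of a group. At day 5 the HOXA means lie between 6.97 and 7.88 with Cre (red) and between 8.42 and 8.89 in the control (blue), and at day 7 Cre array 1 lies at 8.56.

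Exact two-sided permutation tests of the list means per array were added after the data were seen. At day 5 the HOXA, MLL-fusion target, self-renewal and p53 means separated the 5 Cre from the 5 control arrays completely. Their exact p was 0.00794, the smallest that 252 arrangements can give, and 0.0556 after adjustment over the 28 lists. For the granulocyte markers the exact p was 0.0159, and 0.0889 after adjustment. At day 7 the exact p was 0.0286 for the HOXA and MLL-fusion target means, the smallest that 35 arrangements can give, and 0.4 after adjustment. Even with all of them at the smallest p, an adjusted p under 0.05 needs at least 5 lists at day 5 and more than 16 at day 7. None of the 28 lists passed this test at 0.05 after adjustment on any day. The test moves all arrays of a day freely. If the replicate numbers pair the day 5 arrays, the 16 splits that part all pairs cannot give a share under 0.0625.

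At day 7 the HOXA cluster genes were again lower as a group. Of the 9 measured genes 8 were lower with Cre, and the median log2 difference was -1.41. The camera adjusted p was 1.58e-15, and 0.00473 with an estimated correlation, and fry gave 0.0185; over the alternatives it ran from 4.54e-18 to 0.4. In the list 6 were lower when adjusted over the list alone, and 0 passed over all genes. Hoxa10 differed by -2.54 ± 0.54 (SE), Hoxa5 by -1.98 ± 0.55, Hoxa9 by -1.46 ± 0.43 and Hoxa7 by -0.97 ± 0.24.

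The MLL-fusion targets had a median difference of -0.67 at day 7, an adjusted p of 2.85e-09 and 0.0198 with an estimated correlation, while fry gave 0.0840. Over the alternatives that p ran from 1.41e-10 to 0.4. Adjusted over the list alone, 5 targets were lower, and 0 passed over all genes. Meis1 differed by -2.35 ± 0.59 (SE) and Mef2c by -1.37 ± 0.59. Without Cre array 1 of that day Mef2c differed by -2.32, and without Cre array 3 by -0.74. The granulocyte markers had a median of 1.20, with an adjusted p of 1.96e-12, and 0.181 with an estimated correlation, in a range of 1.83e-22 to 0.971 over the alternatives. Without Cre array 1 of day 7 the granulocyte median was 1.74, the adjusted p was 0.0135 with an estimated correlation, and Anxa1 differed by 4.57. No granulocyte marker passed when adjusted over the list alone. Lcn2 and Ltf, which encode secondary granule proteins, differed by 3.25 ± 1.19 and 3.76 ± 1.40, and Anxa1 by 3.01 ± 1.00. The monocyte and macrophage markers, with Fcgr1 at 1.33 ± 0.53 and the complement gene C1qb at 1.09 ± 0.48, had an adjusted p of 0.912 with an estimated correlation. Their mean relative to the other genes, 0.42, was 0.73 and 0.05 without Cre array 1 or 2 of that day, and 0.66 and 0.28 without control array 1 or 3. The preset call ended without Cre array 2 or control array 3, and without Cre array 2 Fcgr1 differed by 0.58 and C1qb by 0.49. With an estimated correlation the adjusted p of the self-renewal genes was 0.305, and for the stress and immediate early genes, with Fos at 1.74 ± 1.18 and Klf6 at 1.02 ± 0.62, it was 0.482. Without control array 3 of that day Fos differed by 1.14 and Klf6 by 0.61.

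Of the 18193 genes tested with limma at day 7, 0 passed, and 580 had an unadjusted p under 0.05 (3.19%). Of the 28 lists 6 passed camera, 2 with an estimated correlation and 1 with fry. The array labelled Cre day 7 replicate 1 had a HOXA mean of 8.56 and a granulocyte mean of 9.70, against 7.10 and 6.82 and against 12.07 and 12.15 on the other Cre arrays. Without it 39 genes passed, Hoxa9, Hoxa10, Meis1 and Anxa1 among them, and 3 lists passed with an estimated correlation. Without the 9 narrow arrays 207 genes passed, in a fit that kept only Cre arrays 2 and 3 and control arrays 3 and 4 of day 7. With array weights 1801 genes passed, with 8 HOXA genes and 17 granulocyte markers among them. In that fit control array 3 of day 7 had a weight of 11.1, against 0.37, 0.19 and 1.93 for control arrays 1, 2 and 4. Cre array 1 had 0.19, against 2.60 and 2.55 for the other Cre arrays. The weighted day 7 counts therefore rest mostly on 1 control array and on Cre arrays 2 and 3. The Cre arrays all lay above the controls in 282 genes and all below in 346, which is 3.45% of genes against 5.71% by chance.

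Whether the Cre effect differed between days was tested directly. No gene passed in limma for day 5 minus day 3, day 7 minus day 5 or day 7 minus day 3, with 352, 150 and 286 genes at an unadjusted p under 0.05. The lists were not tested for a difference between days, so the HOXA and granulocyte values of days 5 and 7 are not shown to differ from those of day 3. With array weights 0, 5 and 288 genes passed.

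The control arrays gave the background of time after transduction without Cre. Between day 5 and day 3, 0 genes passed in limma and 318 had an unadjusted p under 0.05. Between day 7 and day 3, 0 passed and 491 did so unadjusted. The HOXA list mean of the controls was 8.69 ± 0.35 (SD, n = 4) at day 3, 8.66 ± 0.21 (SD, n = 5) at day 5 and 8.77 ± 0.06 (SD, n = 4) at day 7. The granulocyte mean was 9.57 ± 0.78 (SD, n = 4), 9.63 ± 0.84 (SD, n = 5) and 9.77 ± 0.94 (SD, n = 4). With array weights 1252 and 1747 genes passed, the latter with control array 3 of day 7 at a weight of 11.1.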

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

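The tests of outlying arrays followed a rule fixed in advance. They were run on 50 genes selected from those that the naming rule allowed, and on 5 other values per array. The text names most of these genes. Of 275 groups of 4 or 5 arrays tested, 19 held an array far from the others, where chance gives about 1 in 20 groups (5%). All values are log2 intensities, and no explanation was tested for any of them.

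Cre array 2 of day 5 stood apart in 4 genes, with Hoxa5 at 5.746 (others 7.425 to 7.691), Hoxa10 at 7.675 (others 9.036 to 9.474), Hoxa11 at 5.623 (others 6.925 to 7.141) and Plk2 at 8.242 (others 6.256 to 6.747). Control array 1 of day 7 stood apart with Inhba at 8.684 (others 5.037 to 5.26), Anxa1 at 9.967 (others 6.812 to 7.259), Lcn2 at 11.31 (others 6.616 to 7.204) and Nfkbiz at 8.43 (others 5.94 to 6.179). Control array 2 of day 3 had Dot1l at 8.238 (others 8.035 to 8.062), Msr1 at 8.07 (others 7.279 to 7.326) and Pf4 at 10.5 (others 4.679 to 5.492). Cre array 2 of day 3 had Fcgr1 at 7.732 (others 5.681 to 6.103) and Acta2 at 8.527 (others 6.637 to 7.153). Control array 1 of day 3 had Inhba at 7.074 (others 6.011 to 6.182). Control array 2 of day 5 had D130051D11Rik at 9.809 (others 7.793 to 8.344). Cre array 5 of day 5 had Slc2a3 at 9.229 (others 11.22 to 11.97), and Cre array 3 of that day had Csf2rb2 at 8.771 (others 10.01 to 10.38). Control array 2 of day 7 had Setdb1 at 11.11 (others 10.51 to 10.56). The BioB spike-in level of Cre array 1 of day 3 was 13.7, against 10.84 to 11.4 on the others of its group.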

How the results depend on the processing

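The alternatives that left out narrow arrays or dim genes, added the spread as a covariate, combined the weights or the block with other choices, or permuted list means were chosen only after the data were seen. The HOXA, MLL-fusion target, self-renewal and granulocyte lists at day 5 and the HOXA list at day 7 kept their direction and stayed past the threshold in 50 of 51 alternatives. The exact permutation of list means ended all 5 calls, with adjusted p of 0.0556, 0.0556, 0.0556, 0.0889 and 0.4. Even at the smallest p a pass there needs at least 5 lists at day 5 and more than 16 at day 7. The MLL-fusion targets at day 7 did so in 48 and the granulocyte list in 47. The self-renewal list at day 7 did so in 37. These alternatives are not independent, since 26 of them leave out a single array, most often one of another day. Apart from camera with an estimated correlation, fry and the exact permutation, all kept the preset correlation. Inhba stayed past the threshold in 22 of 45 and D130051D11Rik in 16 of 45. The block could not be fitted for the control arrays over time. Dim genes lie near the background, which limits their fold changes. The cause was not tested for any change below.

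Leaving out 1 array at a time gave 0 genes at day 3, 0 to 13 at day 5 and 0 to 39 at day 7, and 0 for the other contrasts. The highest counts of days 5 and 7 came without Cre day 7 replicate 1. The lists passing were 6 to 11 at day 3, 8 to 16 at day 5 and 5 to 10 at day 7. At day 5, 0 genes passed without Cre arrays 1, 4 or 5 of day 3, 1 or 2 of day 5 or 2 of day 7, and without control arrays 3 or 4 of day 3, any of day 5 or 2, 3 or 4 of day 7. The calls of lists below are those of camera. Without Cre array 1 of day 3 the monocyte and cholesterol calls ended (adjusted p 0.102 to 0.106). Without Cre array 2 of day 3 the monocyte and ribosome biogenesis calls ended (adjusted p 0.0921). Without Cre array 3 of day 3 the ribosome biogenesis and stress calls ended (adjusted p 0.121 to 0.138). Without Cre array 4 of day 3 the p53 and ribosome biogenesis calls ended (adjusted p 0.0685 to 0.523). Without Cre array 5 of day 3 the p53, NF-kB and cytokine receptor calls ended (adjusted p 0.0943 to 0.118). Without control array 1 of day 3 the p53 and cytokine receptor calls ended (adjusted p 0.0585 to 0.121). Without control array 2 of day 3 the p53, NF-kB, ribosomal protein, glycolysis, lysosome, cytokine receptor and stress calls ended (adjusted p 0.131 to 0.671). Without control array 3 of day 3 the ribosome biogenesis and cholesterol calls ended (adjusted p 0.0578 to 0.508). Without control array 4 of day 3 the monocyte, NF-kB, ribosome biogenesis, cholesterol and stress calls ended (adjusted p 0.0593 to 0.0923). Without Cre array 1 of day 5 the stroma, replication, mitosis, NF-kB, ribosome biogenesis and ribosomal protein calls ended (adjusted p 0.108 to 0.363). Without Cre array 2 of day 5 the stroma, replication, mitosis, NF-kB, ribosome biogenesis and ribosomal protein calls ended (adjusted p 0.156 to 0.958). Without Cre array 3 of day 5 the cholesterol call ended (adjusted p 0.261). Without control array 3 of day 5 the ribosomal protein call ended (adjusted p 0.107). Without control array 4 of day 5 the stroma, mitosis, ribosome biogenesis, ribosomal protein and cholesterol calls ended (adjusted p 0.0558 to 0.220). Without control array 5 of day 5 the stroma, mitosis, NF-kB, ribosome biogenesis, ribosomal protein and cholesterol calls ended (adjusted p 0.0557 to 0.293). Without Cre array 2 of day 7 the monocyte, self-renewal and stress calls ended (adjusted p 0.0543 to 0.898). Without Cre array 3 of day 7 the self-renewal call ended (adjusted p 0.121). Without control array 3 of day 7 the monocyte, self-renewal and stress calls ended (adjusted p 0.0503 to 0.0817). Without control array 4 of day 7 the self-renewal call ended (adjusted p 0.134).

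With an estimated correlation in camera, 0 lists at day 3, 4 lists at day 5 and 2 lists at day 7 passed. With fry, 0 lists at day 3, 4 lists at day 5 and 1 list at day 7 passed. With only the compared groups fitted, 12 genes at day 5 passed. With the replicate block, 0 genes at day 5 passed. With the replicate number as a random effect across days, 7 genes at day 5 passed. With quantile normalisation applied again, 6 lists at day 3 and 0 genes at day 5 passed. With the mean of the probe sets of a gene, 0 genes at day 5 passed. With the probe set of largest variance, 0 genes at day 5 passed. With a trend and robust variance model, 1 gene at day 5 passed. With array weights, 316 genes at day 5, 9 lists at day 5, 1801 genes at day 7, 11 lists at day 7, 5 genes for day 7 minus day 5, 288 genes for day 7 minus day 3, 1252 control genes at day 5 over day 3 and 1747 control genes at day 7 over day 3 passed. With the narrow arrays left out, 9 lists at day 5, 207 genes at day 7, 12 lists at day 7 and 1 control gene at day 5 over day 3 passed. With the spread as a covariate, 0 genes at day 5 and 8 lists at day 5 passed. With narrow arrays left out and array weights, 1554 genes at day 5, 1040 genes at day 7, 13 lists at day 7, 7 genes for day 7 minus day 5, 127 genes for day 7 minus day 3, 3620 control genes at day 5 over day 3 and 604 control genes at day 7 over day 3 passed. With array weights with Cre day 7 array 1 left out, 1 gene at day 3, 333 genes at day 5, 9 lists at day 5, 2088 genes at day 7, 10 lists at day 7, 16 genes for day 7 minus day 5, 377 genes for day 7 minus day 3, 1292 control genes at day 5 over day 3 and 2267 control genes at day 7 over day 3 passed. With replicate block within each day and array weights, 1503 genes at day 3, 626 genes at day 5, 3 lists at day 7 and 81 genes for day 5 minus day 3 passed. With array spread as covariate and array weights, 605 genes at day 5, 8 lists at day 5, 531 genes at day 7, 11 lists at day 7, 1 gene for day 7 minus day 5, 688 control genes at day 5 over day 3 and 207 control genes at day 7 over day 3 passed. With genes with mean log2 over 8, 5 lists at day 3 and 0 genes at day 5 passed. With genes with mean log2 over 9, 7 lists at day 3, 0 genes at day 5 and 7 lists at day 5 passed. With genes with mean log2 over 10, 3 lists at day 3, 0 genes at day 5, 7 lists at day 5 and 3 lists at day 7 passed. With only the groups compared, with array weights, 277 genes at day 5, 1989 genes at day 7, 12 lists at day 7, 1 gene for day 7 minus day 5, 319 genes for day 7 minus day 3, 786 control genes at day 5 over day 3 and 1184 control genes at day 7 over day 3 passed. With only the groups compared, with replicate block, 68 genes at day 5 passed. With only the groups compared, with replicate block and array weights, 1761 genes at day 3 and 184 genes at day 5 passed. With the exact permutation of list means, 0 lists at day 3, 0 lists at day 5 and 0 lists at day 7 passed.

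The direction of these lists reversed, in mean log2 change relative to all other genes or in the test. For the lysosome list at day 3 (0.2473) it was -0.02156 with array weights, -0.05312 with narrow arrays left out and array weights, -0.02176 with array weights with Cre day 7 array 1 left out, -0.03044 with replicate block within each day and array weights, -0.03263 with only the groups compared, with array weights and -0.03237 with only the groups compared, with replicate block and array weights. For the mitosis list at day 5 (-0.3324) it was -0.00655 with array weights, 0.004797 with the fit without Cre day 5 replicate 2, 0.02176 with narrow arrays left out, 0.05214 with narrow arrays left out and array weights, 0.04029 with array spread as covariate and array weights and -0.004164 with only the groups compared, with array weights, and -0.5323 to 0.004797 with 1 array left out. For the lysosome list at day 7 (-0.005316) it was 0.2866 with the fit without Cre day 7 replicate 1, and -0.2297 to 0.2866 with 1 array left out. For the replication list at day 7 (0.09192) it was -0.3438 with narrow arrays left out, -0.3438 with narrow arrays left out and array weights and -0.2395 with only the groups compared, with array weights, and -0.1893 to 0.3235 with 1 array left out. For the ribosomal proteins list at day 5 (-0.145) it was -0.002504 with narrow arrays left out and array weights. For the cytokine receptors growth signalling list at day 3 (0.2675) it was 0.04041 with replicate block within each day and array weights. For the leukemia self renewal list at day 7 (-0.3874) it was 0.01615 with replicate block within each day and array weights. For the myc ribosome biogenesis list at day 7 (-0.1244) it was 0.4065 with replicate block within each day and array weights, and -0.42 to 0.1152 with 1 array left out.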

Other observations

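The splits of the arrays and the tests of the narrow arrays, of Cre day 7 replicate 1 and of other cells in the sort were chosen only after the result was seen, while the limma and camera values were planned. The genes and bounds of the tests of other cells were revised more than once with the values in view, and earlier bounds had left both explanations open. Some members of the other lists had large differences at days 5 and 7 that did not pass over all genes. Il1rn, the interleukin 1 receptor antagonist gene, differed between Cre and control by 1.99 ± 0.59 (SE, log2) at day 5 and 2.47 ± 0.72 at day 7. For Nfkbiz, a regulator of NF-kB, the values were 1.91 ± 0.63 and 1.59 ± 0.76, and for the glucose transporter gene Slc2a3 1.76 ± 0.62 and 2.03 ± 0.74. The interferon-induced gene Gbp3 differed by -1.64 ± 0.46 and -1.50 ± 0.56, and Prom1, a progenitor marker, by 1.96 ± 0.61 and 2.01 ± 0.73. Setdb1, a histone methyltransferase gene, differed by -0.99 ± 0.36 at day 5, and Aff4, of the elongation complex, by 0.50 ± 0.33. Across the 18193 genes, which are not independent replicates, the differences of days 5 and 7 correlated at r = 0.504, those of days 3 and 5 at 0.152 and those of days 3 and 7 at 0.138.

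The DOT1L complex genes had a median difference of -0.03 at day 5 (camera adjusted p = 0.814). For the Polycomb and other histone methyltransferase genes it was 0.04 (adjusted p = 0.441), while the mean of that list was negative and its test pointed down. The interferon genes had a median of 0.09 and the apoptosis genes one of 0.02, with a negative mean and a test pointing up in the latter. For glycolysis the median was 0.01 with a positive mean and a test pointing down. None of these lists passed at day 5. Without Cre array 2 of day 5, Setdb1 differed by -0.60 and Aff4 by 0.32, and without Cre array 3 of day 7, Gbp3 differed by -0.84. The median, mean and test also differed in sign, without a call, for the progenitor, self-renewal, megakaryocyte, mast cell, dendritic, replication and mitosis lists at day 3. At day 7 this held for the DOT1L complex, progenitor, dendritic, apoptosis, glycolysis, lysosome and cytokine receptor lists.

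The HOXA genes were lower and the granulocyte markers higher at day 5, and other cells in the sort might have diluted the leukemia cells, although the sort on GFP and YFP would remove cells without the leukemia mark. Dilution as the whole cause of the HOXA fall, a median of -1.44, would need markers of the leukemia cells to fall about as much. The median of 10 progenitor markers outside the fusion targets was -0.1452, above the HOXA median by more than their SD of 0.84. They ran from -0.60 (Mycn) to 1.96 (Prom1). These values go against dilution by cells that lack such markers, though the bounds were chosen with the values in view. Dilution by cells that also carry such markers is not covered. Whether a lower share of leukemia cells raised every other cell type alike was examined as well. The B, T and NK, erythroid, mast, megakaryocyte, dendritic and stroma markers measured above the median level of all probe sets (6.52), 41 genes, had a median of 0.1261, below the granulocyte median of 1.88 by more than the SD of either set (0.53 and 1.41), although 17 such monocyte markers had a median of 0.95. The full lists of those other types had mean levels of 5.64 to 6.82 at day 5, near that median, against 10.57 for the granulocyte markers. Small rises could stay hidden there, and a rise of granulocyte or monocyte cells alone is not covered. This comparison therefore does not decide the question. A dilution by cells that carry progenitor markers, one that explains part of the fall, and a change of state in the transduced cells stay open.

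The array labelled Cre day 7 replicate 1 had a HOXA mean of 8.557, close to the controls of its day. A swap with a control array might explain it, but would have left a control with low HOXA levels, and the lowest control was at 8.687 and the other Cre arrays at 7.105 or less. In granulocyte markers, however, control array 1 of day 7 had a mean of 11.14, against 9.09 to 9.58 on the other controls. The HOXA levels alone thus go against a swap. Low RNA input might have hidden the effect. On the narrow Cre arrays of day 5 the highest HOXA mean was 7.876, under the lowest control of 8.425, so a narrow array can still show the fall. Those arrays had BioB levels of 12.14 and 12.05, however, against 12.84 on this array, and came from another day. They therefore do not decide whether low input hid the effect here. A wrong label or cells that kept Dot1l cannot be told apart from other causes, since the Dot1l level of 8.188 lies where Cre and control arrays of day 7 do not separate. On the other Dot1l probe set this array was at 6.894, the lowest of day 7. There too the groups do not separate, with the other Cre arrays at 7.718 and 8.123 and the controls at 7.593 to 8.610.

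Few genes passed at day 7 with all arrays at equal weight, and low RNA input on the narrow arrays may be a cause. Without the 9 narrow arrays 207 genes passed, and 0 of 100 random removals of 9 arrays gave as many, with 97 as the highest. That removal left only Cre arrays 2 and 3 and control arrays 3 and 4 at day 7, so its count rests on few arrays. At day 5 leaving out the narrow arrays gave 2 genes, and 24 of 100 random removals gave as many, with 379 as the highest. The amount of RNA is not in the labels, and the narrow arrays include Cre day 7 replicate 1. Without that array alone 39 genes passed, and without any other array at most 1 did, so these 2 explanations overlap.

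Other splits of the same arrays could test chance only where the real count was above 0, since every split reaches a count of 0. For the real counts above 0 chance could not be excluded. At day 5, 5 of 100 splits gave at least the 2 genes observed (highest other 4815) and 9 of 100 at least 14 lists (highest 17). For the lists of day 3, 16 of 100 gave at least 11 (highest 17), and for those of day 7, 25 of 35 gave at least 6 (highest 15). By camera with its preset correlation the other splits had a median of 7 lists at day 3, 6 at day 5 and 8 at day 7. Several list calls are thus usual for arbitrary splits of these arrays. Where 0 genes passed, all 100 or 35 splits gave as many by construction, which tests nothing. The highest other counts there were 90 genes at day 3, 759 at day 7, 5670, 10340 and 113 for day 5 minus 3, day 7 minus 5 and day 7 minus 3, and 4 and 5 for the control arrays over time.

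With array weights the real day 5 and 7 counts of 316 and 1801 genes were reached by 50 of 100 and 13 of 35 splits, with highest values of 9494 and 5346. At day 3 the real count was 0, with 1674 as the highest of the 100 splits. For day 7 minus day 3 the count of 288 was reached by 22 of 100 (highest 6739). For the controls 1252 and 1747 genes were reached by 47 of 100 and 7 of 35 (highest 7027 and 4142). Counts this far above the real ones point to a structure of the samples. For genes on each of the 3 days, with and without weights, the split with the highest count put all narrow arrays of that day on 1 side. Without the narrow arrays 2 genes passed at day 5 and 207 at day 7 with equal weights, and 1554 and 1040 with array weights. Because the numbers may pair the day 5 arrays, the real split was also set against the 16 splits that part all 5 pairs, which cannot give a share under 0.0625. Among these the real counts were 2 genes (highest other 0) and 14 lists (highest 13), and with array weights 316 genes (highest 288) and 9 lists (highest 13).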
